A study of Mus musculus with 8 samples.

How the data were processed

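Gene expression was measured by RNA sequencing in the small intestine of 14-day-old hUGT1 mice given vehicle or arsenic. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with the Illumina Stranded mRNA kit, and the RNA of 3 mice was pooled for each of 4 libraries per group. Groups were taken from the treatment label, and replicates were numbered within each group only as names. Per the submitters' processing notes, bcl2fastq 2.20, STAR 2.7.9a and DESeq2 1.34.0 were used with the mm10 build. The read counter, the annotation and the strand setting are not given in the sources used here, so that reads of overlapping or antisense genes, and of genes with near-identical copies, cannot be apportioned from the table.

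The authors deposited raw counts for 24411 gene symbols in 8 libraries, of which 4894 were 0 in every library, and these counts were the input of every test made here. The authors also deposited normalized counts, a signal equal to the raw counts divided by 1 factor per library and rounded, and the ratio of both tables lay next to the size factors computed here for each library (for example 1.133 against 1.13 for vehicle replicate 1). The deposited regularized log values are on a log2 scale and were read only to check their unit. The authors' deposited table of the comparison holds log2 fold changes, p-values and adjusted p-values, and marks for 1.5-fold and 2-fold changes. Its calls were compared with those of a DESeq2 run made here on the same counts, in which 9371 genes had an adjusted p below 0.05 and all 9357 of the authors' calls were included. The marks matched DESeq2 tests against the stated fold (1241 of 1242 genes at 1.5-fold and 395 of 395 at 2-fold) and not a plain cutoff, which would mark 3013 genes at 1.5-fold.

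Genes were kept by edgeR's filterByExpr with the group (minimum count 10, minimum total 15), leaving 15298, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, edgeR 4.0.16 in R 4.3.3) on 8 libraries with the group as the only term, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. CPM values are TMM-scaled, and the log2 values used for list tests and components had a prior count of 2. In all, 50 gene lists with 633 genes, of which 575 were tested, were written from textbook knowledge before the data were examined, and each was counted over all genes and over the list alone. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over 47 lists), and again with the correlation estimated in each list. Camera's preset correlation takes genes of a list as nearly independent, so its p-values are small where genes of a list vary together, and the number of lists called was therefore counted over all 35 splits of the libraries as well. Positions, gene identifiers, transcript GC content and lengths came from GENCODE M21 on the mm10 assembly by gene symbol, the stated positions being whole gene spans, exons and introns included.

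The genes named in the text were set by a rule before the data were examined. It took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 5 CPM and no overlap between groups (predicted gene symbols left out), a fixed panel of 26 genes whatever their result, and up to 4 members with the smallest p of each list. Some genes that the rule takes are not reported here. Other genes are named only where few members of a list moved against the rest, and were chosen after their values were seen: Gclm, Fth1, Vegfa and Adm in the lists, and the genes of the other observations. Gene families in those observations were formed by symbol, and the kinase genes with symbols starting Rps6k were taken out of the Rps family after the table had been seen, since they are not ribosomal proteins.

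Totals ran from 18786779 to 29417666 counts per library, and changes of genes near 1 CPM were the less precise ones, for example Cd8a at log2 -1.11 (SE 0.20), Gzma at -1.70 (SE 0.29) and Gzmb at -1.81 (SE 0.36). In counts simulated from these libraries with 200 changed genes, the test recovered 54% of 1.2-fold, 96% of 1.5-fold and 100% of 2-fold changes, with 18 false calls among 15206 genes tested. Those 18 stood beside 27, 48, 50 and 50 recovered genes at 1.2-fold, 1.5-fold, 2-fold and 4-fold. The changed genes were all taken from better-counted ones and were far fewer than the real calls. These rates therefore do not describe low-level genes or the real comparison. Pairs of libraries of a group differed by more than sampling noise (chi-square per degree of freedom 3.06 to 14.0), so no library appeared to be deposited in duplicate, and each was counted as a separate sample because the labels describe separate pools. The first principal component held 75.5% of the variance and separated the groups, the second 5.42%. The labels give no sequencing batch, litter or cage, and p-values measure the spread between pools of 3 animals, which average over animals.

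Alternatives set beforehand were DESeq2 size factors and upper-quartile factors in edgeR, no filter, a filter of 1 CPM in 4 libraries, leaving out each library, a surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma-voom, robust quasi-likelihood, a test against a 1.5-fold change, camera with an estimated correlation and fry. Added after seeing the data were the Y-linked expression of each pool as a covariate, leaving out both pools that looked single-sex, and removal of GC content and length trends. Camera results were followed across the alternatives for the 16 lists it called. For the other lists only the counts of higher and lower members were followed, a choice made after seeing that the camera direction of several of them changed sign. No sample was left out of the main result. Ass1, Eno1 and the globin genes had 3 or fewer counts in total and were not tested, and mitochondrially coded genes were not analysed here.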

Results

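RNA of the small intestine was sequenced from mice of the hUGT1 line, a transgenic line that carries the human UGT1 locus coding for UDP-glucuronosyltransferases. The pups were 14 days old, an age at which mice are still suckling, and had been given vehicle or arsenic at 10 mg/kg, with 24 h as the labelled time. Each group held 12 mice, whose RNA was pooled from 3 animals per library, so that 4 vehicle libraries were compared with 4 arsenic libraries. The series title places the comparison in the study of enterocyte lipid, tissue growth and intestinal maturation under arsenic during suckling. Total counts per library ran from 18786779 to 27369320 with vehicle and from 22630208 to 29417666 with arsenic, and 17701 to 18082 genes had counts in a library. Values for genes are TMM-normalized CPM given as mean ± SD of n = 4 pools, and log2 fold changes are arsenic over vehicle.

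Expression in the small intestine differed broadly between arsenic and vehicle. Most listed targets of the oxidative stress regulator NRF2 rose, led by the glutathione S-transferase gene Gsta1, while all tested genes of the suckling-type list fell, among them those of the neonatal Fc receptor (Fcgrt), lactase (Lct) and lysosomal enzymes. Sucrase-isomaltase (Sis) and arginase 2 (Arg2), which normally come up at weaning, were already higher. Most tested genes of cell division, ribosome assembly, cholesterol synthesis and glycolysis rose, and most interferon-induced genes and markers of T cells, macrophages and blood vessels fell. Of the 15298 genes tested, 4944 were higher and 5053 lower in arsenic at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), together 65.3%. TMM scaling takes most genes as unchanged, so the near-even split and the sign of the smallest changes rest on it. At least 1.5-fold changes were fewer, with 1399 genes higher and 1622 lower, and at least 4-fold changes were seen for 60 higher and 98 lower genes. The values of the 4 arsenic pools lay entirely above or below those of the 4 vehicle pools for 59.4% of the tested genes, where chance gives 2.86%. A test against a 1.5-fold change (glmTreat) left 815 genes higher and 814 lower. The pools differed in their sex makeup within both groups, and without vehicle replicate 4 and arsenic replicate 3, whose Xist and Y-linked counts stood at the extremes, 4664 genes were higher and 4740 lower.

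Among genes with a mean of at least 5 CPM and no overlap between groups, predicted gene symbols aside, the strongest rise was that of Serpinb9b, a serine protease inhibitor, from 0.766 ± 0.203 to 84.3 ± 20.8 CPM (log2 6.77, SE 0.23, adjusted p = 5.74e-12). Serpinb9b lies on chromosome 13 of the mm10 build between positions 33027416 and 33041884 on the plus strand (ENSMUSG00000021403). Next came Gsta1, a glutathione S-transferase on chromosome 9 from 78230656 to 78242684 (ENSMUSG00000074183), which rose from 6.09 ± 1.11 to 246 ± 24.6 CPM, 39.6-fold. The aldo-keto reductase Akr1b8 rose 21.9-fold and the sodium-coupled transporters Slc5a4b and Slc5a12 rose 17.2-fold and 13.5-fold. Among the 12 genes with the strongest rise were also Gsta4 (log2 3.85), Gsta2 (3.53), Gstm3 (3.27), the protease Pappa2 (3.76), the cornified envelope gene Sprr1a (2.83) and the regenerating proteins Reg2 (3.57) and Reg3b (2.77). At the other end, complement component C8b fell from 23.0 ± 2.53 to 0.753 ± 0.202 CPM (log2 -4.92, adjusted p = 1.55e-12), followed by the noncoding Dio3os (-4.39), the secreted protein Lect2 (-3.95), the water channel Aqp8 (-3.69) and Cym (-3.62), which codes for the milk-clotting protease chymosin. Dct fell by 3.50 on the log2 scale, and the apolipoprotein L gene Apol10a by 3.11. Gsta1, Gsta2, the other glutathione S-transferases and the Reg genes have close relatives, and how reads shared between such copies were counted is not given in the sources used here.

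Most genes under the oxidative stress regulator NRF2 rose. Of the 29 tested members of that list 25 rose and 2 fell, with a median log2 change of 1.03, and 26 rose and 2 fell when adjusted over the list alone. Nqo1, a quinone reductase on chromosome 8 from 107388225 to 107403206, rose 3.02-fold from 22.4 ± 1.35 to 67.7 ± 6.99 CPM, Gclc, the catalytic subunit of glutathione synthesis, rose 2.48-fold and Srxn1, which repairs peroxiredoxins, 1.58-fold. The members that fell were Gclm (log2 -0.44), the other subunit of the glutathione-forming enzyme, and the ferritin heavy chain Fth1 (-0.27). The list stood apart from other genes in the camera test (adjusted p = 1.59e-09, and adjusted p = 0.547 with an estimated correlation). Hmox1, the heme-degrading enzyme, stood at 34.8 ± 16.2 CPM with vehicle and 49.5 ± 14.5 CPM with arsenic and missed the threshold (log2 0.53, adjusted p = 0.0661). Its result moved both ways with single pools, the highest being vehicle replicate 4 at 58.7 CPM and arsenic replicate 1 at 70.9 CPM. With 1 library left out, its log2 change ranged from 0.30 to 0.91 and its adjusted p from 0.000454 to 0.267. Hmox1 passed when vehicle replicate 4 was left out (log2 0.91, adjusted p = 0.000454), or arsenic replicate 3 (log2 0.62, adjusted p = 0.0474) or arsenic replicate 4 (log2 0.63, adjusted p = 0.0398). It also passed without a filter on low counts (adjusted p = 0.0294), with a surrogate variable (0.0498), in limma-voom (0.0305), with Y-linked expression as a covariate (0.000458) and without both pools that looked single-sex (0.00032). In the metal response list 3 of 7 genes rose and 2 fell (camera adjusted p = 0.990). The metallothionein Mt1 rose by log2 0.28 and the low-level Mt3 by 1.25, Mt2 stood at -0.15 (adjusted p = 0.192, but 0.00658 with Y-linked expression as a covariate and 0.00501 with GC content and length trends removed), and the zinc exporters Slc30a1 and Slc30a2 fell by 0.46 and 0.68 on the log2 scale.

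Most listed heat shock and endoplasmic reticulum chaperone genes rose. Of 18 heat shock genes 14 rose and none fell (median log2 0.57, camera adjusted p = 3.74e-05, and adjusted p = 0.547 with an estimated correlation), led by the mitochondrial chaperonins Hspd1 (log2 1.36) and Hspe1 (1.05) and by Hsp90aa1 (1.07). Of 16 endoplasmic reticulum chaperone genes 14 rose and 2 fell (median log2 0.77, camera adjusted p = 0.000232, and adjusted p = 0.547 with an estimated correlation), with Manf at 1.00, Hyou1 at 0.97 and Pdia4 at 0.77. Only 1 was lower without vehicle replicate 2 or 3 or arsenic replicate 3, without both pools that looked single-sex or with GC content and length trends removed. In the integrated stress response list 12 of 22 genes rose and 4 fell, which did not pass the camera test (adjusted p = 0.0771). The serine synthesis genes Psat1 (log2 1.81) and Phgdh (1.42) and the mitochondrial folate gene Shmt2 (1.21) rose, and Aldh18a1, which starts proline synthesis, fell by 1.02 on the log2 scale. The p53 target list was divided, with 6 of 16 genes higher, such as the cell cycle inhibitor Cdkn1a (0.62) and Aen (0.93), and 6 lower, such as Trp53inp1 (-1.33) and Pmaip1 (-0.68), and did not pass (camera adjusted p = 0.990). The counts of the heat shock, chaperone, stress response, p53 and metal lists were the same when adjusted over the list alone.

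Among genes that handle foreign compounds, several conjugating enzymes and efflux pumps rose, and the cytochromes Cyp3a11 and Cyp3a25 fell. The UDP-glucuronosyltransferase list had 6 of 8 tested members higher and 1 lower (median log2 0.83, camera adjusted p = 0.0101, and adjusted p = 0.302 with an estimated correlation). Ugt2b5 rose 2.53-fold, Ugt2b36 2.12-fold and Ugt2b34 from 372 ± 4.98 to 751 ± 33.5 CPM, whereas counts assigned to the mouse symbol Ugt1a1 fell from 8.69 ± 0.405 to 6.82 ± 0.616 CPM. The human UGT1 genes of these mice were not analysed here. How their reads were counted is not given in the sources used here, so that the counts under Ugt1a1 can include reads of the human genes. Among 11 targets of the drug sensors PXR and CAR 6 rose and 3 fell (camera adjusted p = 0.313), with the efflux pumps Abcb1a at log2 2.02 and Abcc3 at 1.58 and the cytochromes Cyp3a11 at -2.15 and Cyp3a25 at -1.47. The arsenic handling list had 6 of 10 genes higher and 2 lower (camera adjusted p = 0.279), including the channel Aqp3 (1.84), the arsenic methyltransferase As3mt (0.62) and the phosphate transporters Slc20a1 (0.79) and Slc34a2 (-0.83). Of 4 tested AHR targets Nfe2l2 rose by log2 0.25, and Tiparp (-0.22) and Ahrr (-0.67) fell (camera adjusted p = 0.990). The counts of these lists were unchanged when adjusted over the list alone, except that 2 AHR targets then rose.

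Digestive genes of the suckling gut fell and most genes listed for the weaned gut rose. All 14 tested genes of the suckling-type list fell, also when adjusted over the list alone (median log2 -1.21, camera adjusted p = 7.88e-08, and adjusted p = 0.302 with an estimated correlation). Fcgrt, which carries maternal antibodies across the epithelium, fell from 2131 ± 272 to 182 ± 5.38 CPM, 11.7-fold lower (chromosome 7, 45092990 to 45103851, minus strand). Lct on chromosome 1 (128284756 to 128328318) fell from 3630 ± 285 to 1605 ± 181 CPM. The lysosomal proteases Ctsl and Lgmn, which digest milk proteins taken up whole, fell by 2.58 and 1.79 on the log2 scale, the lysosomal galactosidase Glb1 by 0.85, and Prdm1, the repressor that holds the fetal and suckling programme, by 1.66. Ass1, an arginine synthesis gene of the suckling gut, had 3 counts over all libraries and was not tested. The globin genes and Eno1 were as low, and how multi-mapped reads were counted is not given in the sources used here, so that these counts do not show whether Ass1 was expressed. Of 7 adult-type genes 5 rose and 1 fell, also when adjusted over the list alone (median log2 0.92, camera adjusted p = 0.0385, and adjusted p = 0.620 with an estimated correlation). Sis on chromosome 3 (72888557 to 72967863) rose 3.11-fold from 479 ± 33.8 to 1488 ± 192 CPM, the maltase Mgam rose 2.54-fold, Arg2 2.41-fold and the villus-tip keratin Krt20 1.90-fold. Krt20 is also a member of the brush border list, so its rise does not speak for the weaned gut alone. Treh, the trehalase of the adult brush border, went the other way, from 99.0 ± 13.1 to 83.4 ± 10.5 CPM with overlapping groups (adjusted p = 0.0292). It lost its call when vehicle replicate 2 (adjusted p = 0.139), vehicle replicate 3 (0.0721), vehicle replicate 4 (0.0803), arsenic replicate 1 (0.0502) or arsenic replicate 3 (0.0935) was left out. It also lost it in DESeq2 (adjusted p = 0.129), with the robust fit (0.143), with Y-linked expression as a covariate (0.0562) and without both pools that looked single-sex (0.170). The camera call of the adult-type list ended when genes had to reach 1 CPM in 4 libraries (adjusted p = 0.0503) or with a surrogate variable in the model (adjusted p = 0.0507).

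**Figure D1:**
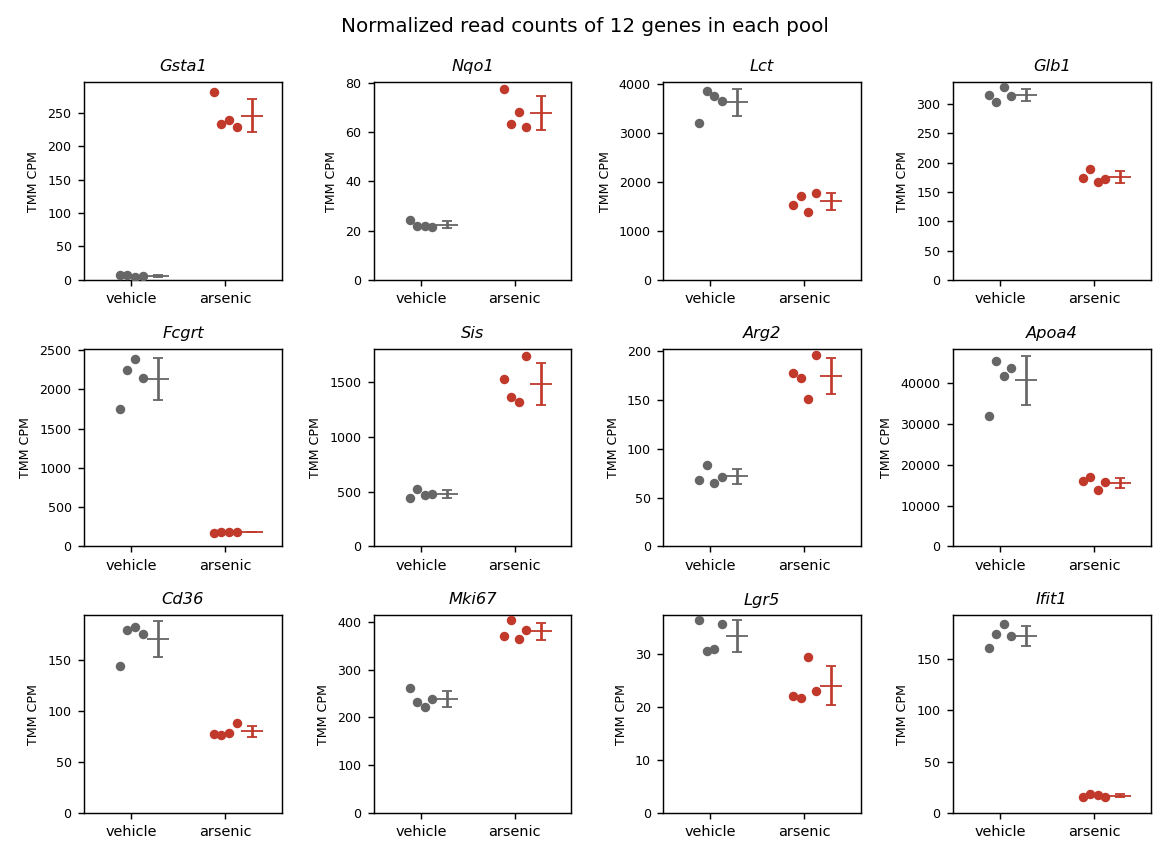
Normalized counts (TMM CPM, linear axis from 0) of 12 genes in each of the 4 vehicle pools and 4 arsenic pools, as points, with the mean and SD of each group beside them. The groups do not overlap for any of the 12 genes, and Fcgrt, for example, stood at 2131 ± 272 CPM with vehicle and 182 ± 5.38 CPM with arsenic.

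Beside these changes, the brush border list, which marks absorptive enterocytes at either age, was divided, with 9 of 18 genes higher and 7 lower (camera adjusted p = 0.631). The aminopeptidases Anpep and Enpep rose by log2 1.00 and 0.90, Dpp4 rose by 0.79, and the metalloprotease Mep1a fell by 0.93. Genes that mark position along the small intestine moved as well. Of 5 proximal genes 4 fell and 1 rose (median log2 -0.71, camera adjusted p = 0.0416, and adjusted p = 0.547 with an estimated correlation), with the iron reductase Cybrd1 at -3.35, Slc40a1 at -1.65, Onecut2 at -0.71 and the duodenal factor Pdx1 at -0.59. Cybrd1 and Slc40a1 are also members of the iron and heme list, so their falls do not speak for position alone. The camera call of the proximal list ended without arsenic replicate 3 (adjusted p = 0.0503) or with a surrogate variable (adjusted p = 0.0507). No proximal gene was higher without vehicle replicate 1 or 4 or arsenic replicate 1 or 2, without both pools that looked single-sex or with upper-quartile scaling. Of 6 distal genes 4 rose and 2 fell (camera adjusted p = 0.408). The ileal bile acid transporter Slc10a2 rose from 3.13 ± 1.05 to 21.5 ± 2.49 CPM, the bile acid binding protein Fabp6 rose 2.38-fold and Slc51b 1.57-fold, while the ileal hormone Fgf15 fell by 0.73 on the log2 scale (SE 0.07). Counts of these 3 lists were the same when adjusted over the list alone. The labels do not say which part of the small intestine was taken.

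Fat-handling genes did not move as a block. In the list of fat absorption and chylomicron genes 8 of 20 rose and 9 fell (9 and 9 when adjusted over the list alone, camera adjusted p = 0.704). Apoa4, an apolipoprotein of intestinal fat particles on chromosome 9 (46240696 to 46243459), was among the most abundant transcripts and fell from 40762 ± 6025 to 15609 ± 1253 CPM. It took between 3.30% and 4.46% of all counts with vehicle and between 1.42% and 1.68% with arsenic. Apoc3 fell by 1.75 on the log2 scale, the cholesterol transporter Npc1l1 by 1.13 and the fatty acid transporter Cd36 by 1.09, while Mttp, which loads fat onto chylomicrons, rose 1.46-fold and Sar1b, needed for their export, 1.73-fold. Of 16 lipid droplet genes 4 rose and 8 fell (camera adjusted p = 0.754). The droplet coat gene Plin2 fell from 387 ± 21.3 to 320 ± 34.9 CPM, Lipe fell by 0.43 and Acsl3 by 0.65 on the log2 scale, and the lipase inhibitor G0s2 rose 2.98-fold and Fitm2 1.91-fold. PPARA targets and fatty acid oxidation genes were divided, with 8 of 21 higher and 7 lower (camera adjusted p = 0.990). Cyp4a10 fell by 1.77 on the log2 scale, Pdk4 by 0.31 with overlapping groups and Ehhadh by 0.57, and the lipase inhibitor Angptl4 rose 2.97-fold. Cpt1a, which admits fatty acids to mitochondria, stood at 508 ± 18.1 and 539 ± 44.2 CPM (adjusted p = 0.197) and passed the threshold without arsenic replicate 3 (log2 0.14, adjusted p = 0.0107). Fatty acid synthesis genes were divided too, with 6 of 16 higher and 7 lower (camera adjusted p = 0.990), the synthase Fasn at log2 0.56, Me1 at 0.80, Acaca at 0.39 and the regulator Srebf1 at -0.85. Most cholesterol synthesis genes rose, 21 of 24 with 1 lower, which was not called without vehicle replicate 2 or 3 or arsenic replicate 4, without a filter, in DESeq2, without both pools that looked single-sex or with GC content and length trends removed (median log2 0.39, camera adjusted p = 2.70e-05, and adjusted p = 0.547 with an estimated correlation). Idi1 rose 1.95-fold, Msmo1 1.72-fold and Hsd17b7 1.63-fold. The counts of the droplet, oxidation, fatty acid and cholesterol lists were the same when adjusted over the list alone.

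Most listed genes of the cell cycle, ribosome biogenesis, glycolysis and nuclear-coded oxidative phosphorylation rose, and growth factor genes were divided. All 22 cell cycle genes rose (median log2 0.81, camera adjusted p = 1.24e-09, and adjusted p = 0.547 with an estimated correlation), with the proliferation marker Mki67 rising 1.59-fold, the nucleotide reductase subunit Rrm2 rising 2.92-fold, Plk1 2.14-fold and Cdk1 1.90-fold. Of 15 ribosome biogenesis genes 14 rose and none fell (median log2 0.83, camera adjusted p = 9.52e-07, and adjusted p = 0.547 with an estimated correlation), among them Npm1, Ddx21 and Nolc1 at log2 1.05, 1.04 and 0.97. The glycolysis and hypoxia list had 12 of 15 genes higher and 2 lower (median log2 0.77, camera adjusted p = 0.000308, and adjusted p = 0.547 with an estimated correlation). Its risers were mostly glycolytic enzymes such as Pgk1 (2.67-fold), Aldoa (2.43-fold), Gapdh (2.24-fold) and Pkm (1.99-fold), and the members that fell were the hypoxia-induced Vegfa (log2 -0.71) and Adm (-0.50). Nuclear-coded genes of oxidative phosphorylation rose in 18 of 19 cases (median log2 0.47, camera adjusted p = 2.16e-06, and adjusted p = 0.547 with an estimated correlation), with Cyc1 at 0.81 and Cox5a at 0.80. The 13 mitochondrially coded members were not analysed here. Of the growth factor genes 5 of 11 were higher and 5 lower (camera adjusted p = 0.990), the EGF family ligands Ereg and Nrg1 rising 4.22-fold and 3.29-fold and Igf2 and Igf1r falling by 0.91 and 0.43 on the log2 scale. Counts of all 5 lists were the same when adjusted over the list alone.

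**Figure D2:**
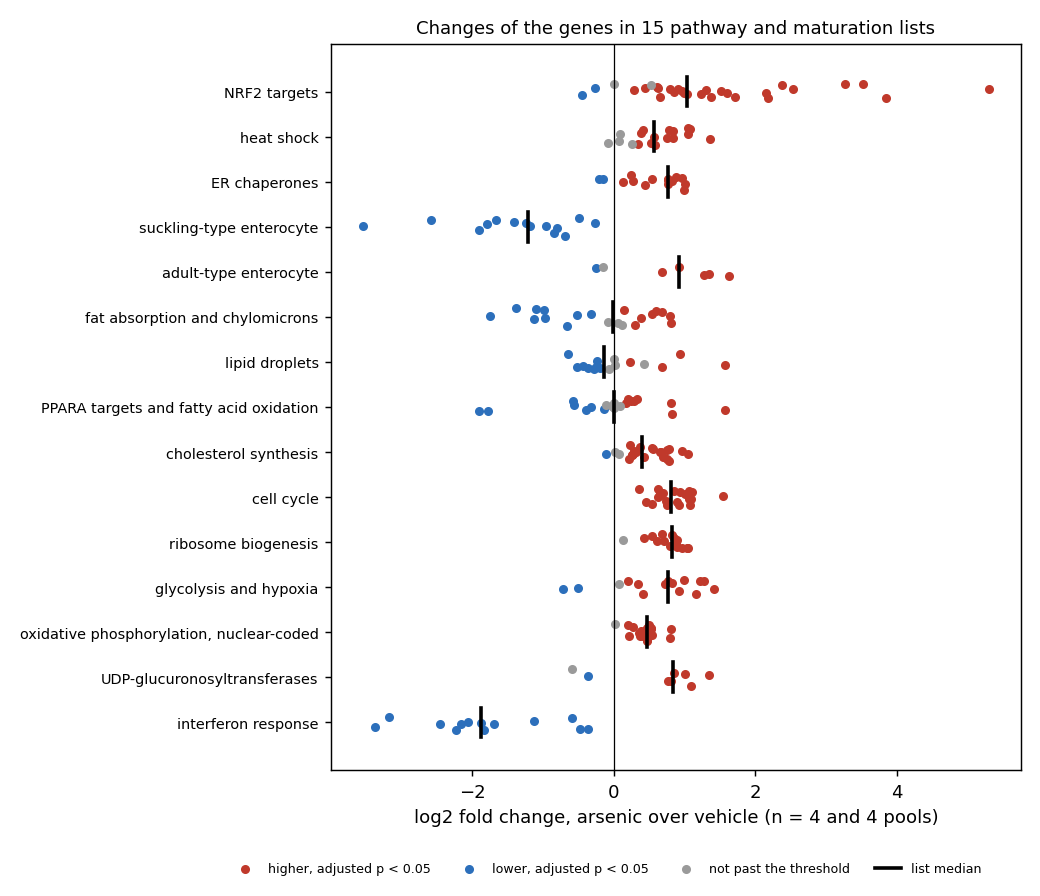
Log2 fold change of arsenic over vehicle (x axis) for each tested gene of 15 lists (rows), 1 point per gene, coloured by whether it was higher, lower or not past an adjusted p of 0.05, with a bar at each list's median. The 14 suckling-type and 13 interferon genes all lie to the left of 0 and the 22 cell cycle genes all to the right.

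Markers of the epithelial lineages moved in different directions. Stem cell genes were lower in 6 of 11 cases and higher in 1, a list result that did not pass (camera adjusted p = 0.105). Lgr5 fell from 33.4 ± 3.08 to 24.0 ± 3.63 CPM, Rnf43 fell by 0.81 on the log2 scale, Axin2 by 0.60, Olfm4 by 0.48 and Sox9 by 0.41. Goblet cell genes rose in 6 of 10 cases with 1 lower, which was not called with size-factor scaling, without vehicle replicate 2, 3 or 4 or arsenic replicate 1, 3 or 4, with Y-linked expression as a covariate or without both pools that looked single-sex (camera adjusted p = 0.184), including Agr2 (2.08-fold), the mucin Muc2 (1.46-fold), Spink4 and Zg16. Of 9 Paneth cell genes 4 fell, among them Defa22 and Itln1 (log2 -0.28 and -0.26), and Mmp7 rose (camera adjusted p = 0.552), with the Defa genes being near-identical copies whose counts are uncertain. Of 14 enteroendocrine genes 6 fell, such as Chga (-0.52), Gip (-0.63) and Sst (-0.41), and 3 rose (camera adjusted p = 0.441). Tuft cell genes fell in 5 of 7 cases, with Trpm5 at -0.63 and Pou2f3 at -0.72 (camera adjusted p = 0.0907). Counts of these 5 lists were the same when adjusted over the list alone.

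Interferon-induced genes fell in every tested case. All 13 members of that list were lower, also when adjusted over the list alone (median log2 -1.88, camera adjusted p = 7.11e-08, and adjusted p = 0.302 with an estimated correlation). Ifit1 on chromosome 19 (34640871 to 34650009) fell from 173 ± 9.75 to 16.6 ± 1.53 CPM, 10.4-fold lower, Ifit3 was 9.07-fold lower, Rtp4 4.44-fold lower and Oasl2 3.57-fold lower. Ifit2, from the same gene cluster, fell by 3.17 on the log2 scale. Of the immune cell lists, camera with the preset correlation called those of T and NK cells and macrophages lower, and not those of B cells, mast cells and neutrophils. The difference between lists was not tested, and the B cell median (log2 -0.55) was as low as the macrophage median (-0.52). All 9 tested T and NK cell genes fell (median 0.501 of the vehicle level, camera adjusted p = 0.0136, and adjusted p = 0.302 with an estimated correlation), with Cd4 going from 11.6 ± 0.464 to 6.89 ± 0.803 CPM and Cd8a, Gzma and Gzmb at -1.11, -1.70 and -1.81. This list's call ended when genes had to reach 1 CPM in 4 libraries (adjusted p = 0.0727), which left 4 members lower. Of 10 macrophage genes 8 fell, among them Cx3cr1 (-0.70), C1qc (-0.64), C1qb (-0.61) and Csf1r (-0.56), with a camera adjusted p = 0.0197 and adjusted p = 0.547 with an estimated correlation. All 7 B cell genes were lower, at low levels, with Pou2af1 at -0.71 (camera adjusted p = 0.213), but 4 or fewer passed when vehicle replicate 1, 2 or 3 or arsenic replicate 1, 2 or 4 was left out, 2 without arsenic replicate 1, and 4 in DESeq2. Of 5 mast cell genes Mcpt1 (-0.58) and Mcpt2 (-0.48) fell (camera adjusted p = 0.445), the call of Mcpt2 being lost without both pools that looked single-sex (adjusted p = 0.0791), and of 3 neutrophil genes Cxcr2 was lower at an adjusted p of 0.0467, a call that was lost with vehicle replicate 1, 3 or 4 or arsenic replicate 1 or 4 left out, without a filter, in DESeq2, with a surrogate variable, with Y-linked expression as a covariate or without both pools that looked single-sex (camera adjusted p = 0.842). Counts were the same when adjusted over the list alone, except that no neutrophil gene then passed.

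Inflammation genes were divided, with 5 of 15 higher and 7 lower, also when adjusted over the list alone (camera adjusted p = 0.990), and 4 lower without vehicle replicate 4 or with a minimum of 1 CPM in 4 libraries. Without both pools that looked single-sex 6 were higher and 4 lower. The antimicrobial lectins Reg3b and Reg3g rose 6.83-fold and 6.18-fold and the iron-binding Lcn2 2.01-fold, while the chemokine Ccl20 fell by 1.13 on the log2 scale. Endothelial genes fell in 9 of 10 cases with 1 higher (median log2 -0.45, camera adjusted p = 0.00614, and adjusted p = 0.547 with an estimated correlation), including Cdh5 (-0.53), Vwf (-0.51), Kdr (-0.49) and Pecam1 (-0.46). Smooth muscle genes rose in 8 of 11 cases and fell in none (camera adjusted p = 0.0616), with Cnn1 at 0.55, Actg2 at 0.44, Acta2 at 0.42 and Tagln at 0.39. Fibroblast genes moved little. Lum (-0.14) and Dcn (-0.10) were lower among 8 members, none passed when adjusted over the list alone (camera adjusted p = 0.676), and Col3a1 stood at 1289 ± 66.7 and 1203 ± 88.8 CPM (adjusted p = 0.140), passing without arsenic replicate 3 (log2 -0.15, adjusted p = 0.0179). The calls of Lum and Dcn were each lost with vehicle replicate 3, arsenic replicate 2 or arsenic replicate 4 left out and in DESeq2. That of Dcn was also lost without vehicle replicate 4 or arsenic replicate 1, with size-factor scaling, under either other filter and with Y-linked expression as a covariate. Of 11 enteric nervous system genes the receptor Ret fell by 1.39 and the glial S100b by 2.04 on the log2 scale, the low-level glial Gfap rose by 1.36, and the other 8 did not pass (camera adjusted p = 0.990), with 3 higher without vehicle replicate 4 and 2 without arsenic replicate 1. Counts of the endothelial, smooth muscle and nerve lists were the same when adjusted over the list alone.

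**Figure D3:**
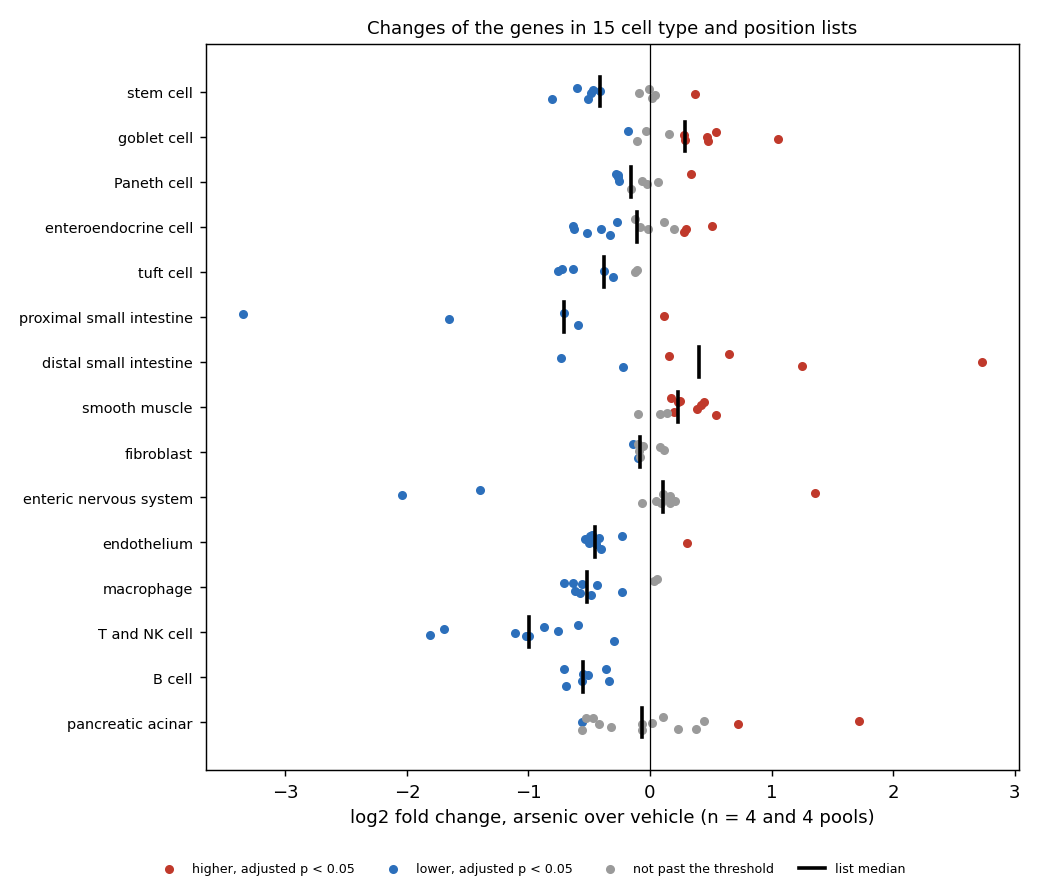
Log2 fold change of arsenic over vehicle (x axis) for each tested gene of 15 cell type and position lists (rows), 1 point per gene, coloured by whether it was higher, lower or not past an adjusted p of 0.05, with a bar at each list's median. The 9 T and NK cell and 7 B cell genes lie to the left of 0, and the smooth muscle genes mostly to the right.

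RNA of neighbouring organs was looked for with further lists. Of 15 pancreatic acinar genes 2 were higher and 1 lower (1 and 0 when adjusted over the list alone, camera adjusted p = 0.990). With GC content and length trends removed 1 was higher and 4 were lower. Genes of pancreatic digestive enzymes varied between pools of 1 group, with the lipase gene Cel at 1154 ± 372 and 783 ± 311 CPM, and the trypsin genes Try4 at 211 ± 76.7 and 349 ± 158 CPM and Try5 at 85.0 ± 31.4 and 282 ± 96.6 CPM, and 6 acinar genes were lower without arsenic replicate 4. The call of Try4 was lost without vehicle replicate 3 or 4 or arsenic replicate 4 and with GC content and length trends removed. That of Cel was lost without vehicle replicate 1 or 2 or arsenic replicate 1, 2 or 3, at a minimum of 1 CPM, with a surrogate variable and without both pools that looked single-sex. Both were lost in DESeq2 and with the robust fit. Of 5 liver genes Serpina1a (-2.82), Fgb (-1.16) and Fga (-0.76) fell (camera adjusted p = 0.123), and of 6 adipocyte genes Lpl rose by log2 0.52 and Retn stood at 0.571 ± 0.244 and 0.242 ± 0.136 CPM, a call lost without vehicle replicate 2, 3 or 4, arsenic replicate 1 or 3 or both pools that looked single-sex (camera adjusted p = 0.704). The only tested erythroid gene, Alas2, fell by 1.14 on the log2 scale. Counts of these 3 lists were the same when adjusted over the list alone.

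Iron, clock and hormone-response genes changed individually. In the iron and heme list 4 of 11 genes rose and 5 fell (5 and 5 when adjusted over the list alone, camera adjusted p = 0.990). The intestinal iron importer Slc11a2 fell from 806 ± 11.2 to 290 ± 41.8 CPM, the reductase Cybrd1 from 297 ± 34.7 to 29.1 ± 5.44 CPM and the exporter Slc40a1 was 3.15-fold lower, while Alas1, the first enzyme of heme synthesis, rose 1.80-fold. Of 9 glucocorticoid response genes Fkbp5 rose 3.44-fold and 4 fell, including Cdkn1c (-1.27), Tsc22d3 (-0.65) and Klf9 (-0.28), which did not pass as a list (camera adjusted p = 0.355). Of 13 clock genes 3 rose and 6 fell (camera adjusted p = 0.704), with Nr1d1 at 1.10, Npas2 at -0.69 and Tef at -0.64, and Per2 fell from 126 ± 6.31 to 63.5 ± 11.8 CPM. None of the 5 sex-specific genes passed the edgeR test (0 also at an unadjusted p under 0.05), Xist standing at 857 ± 416 and 560 ± 444 CPM and Ddx3y at 25.8 ± 19.5 and 39.3 ± 24.5 CPM. The counts of the clock, glucocorticoid and sex lists were the same when adjusted over the list alone. The median and mean log2 change differed in sign for the metal, p53, droplet, growth factor, enteric nervous system, acinar, inflammation, AHR and iron lists, and the camera direction of the oxidation list was opposite to both.

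Across the 47 lists that could be tested, camera with a preset correlation found 10 higher and 6 lower, and none passed when the correlation was estimated in each list (lowest adjusted p = 0.302, with 4 lists at an unadjusted p under 0.05). The directional test of fry passed 33 lists. Unlike camera, fry asks whether a list's genes changed between groups, without comparing them with other genes. With 65.3% of all tested genes past the threshold, its count cannot be set against that of camera. The number of lists that camera called was also reached when the 8 libraries were regrouped, since 9 of the 35 splits into 4 and 4, the real one included, gave 16 or more lists, up to 21. The other splits that reached it all set 3 vehicle pools against 1 and so keep part of the group difference, and the 18 splits with 2 vehicle pools on each side gave between 1 and 8 lists. No split other than the real one gave a gene past the threshold (edgeR, and 0 in limma-voom, with up to 1065 genes at an unadjusted p under 0.05). All of these other splits mix vehicle and arsenic pools, which widens the spread within their sides and holds their counts down. A total of 9357 genes had an adjusted p below 0.05 in the authors' deposited table, 4851 higher and 4506 lower. Of these 9222 were among the genes called here with edgeR, all with the same sign. Marks for a 1.5-fold change stood at 1241 genes and for a 2-fold change at 395 in the authors' deposited table, 154 of the latter higher and 241 lower.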

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

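The tests of enterocyte share, position along the gut, dilution by epithelium and immune cell RNA below were chosen only after the result was seen, as were the division of the splits by their number of vehicle pools and the fits with Y-linked expression and with GC content and length trends removed. The permutation p-values come from lists whose changes were already known, so they add no independent support to those changes.

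The number of changed genes was very large, 9997 of 15298 tested. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes, the real one, and the highest of the other splits gave 0 (edgeR, and 0 with limma-voom, with up to 1065 genes at an unadjusted p under 0.05). Every other split mixes vehicle and arsenic pools, so the group difference widens the spread within its sides and holds its count down. To rank 1 of 35 is the most that this tally can give. It argues against chance for the number of genes but does not exclude it. Nor can chance be excluded for the number of lists called by camera with a preset correlation, since 9 of the 35 splits gave at least the real 16 and the highest of the others gave 21, although the 16 splits that set 3 vehicle pools against 1 keep part of the group difference, and the 18 with 2 vehicle pools on each side gave between 1 and 8 lists. Unequal sex makeup of the pools is argued against as the whole cause because 97.0% of the calls were kept with Y-linked expression as a covariate, and GC content or transcript length bias because 91.3% were kept with those trends removed. Arsenic against vehicle was the planned comparison. An effect of arsenic cannot be told apart from a difference of batch, litter or cage, none of which the labels name.

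Suckling-type genes were lower and most adult-type genes higher in arsenic. A smaller share of enterocytes would lower brush border genes as well, but the suckling-type mean minus the brush border mean was lower in every arsenic pool than in every vehicle pool, by -1.50 on the log2 scale (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 can give). The brush border list was itself divided, with 9 of 18 genes higher and 7 lower, and shares Krt20 with the adult-type list. Of 11 called position genes, 8 (72.7%) went the way of a distal shift, Slc10a2 among them, and 3, Fgf15 among them, did not (exact binomial test against an even split, two-sided, p = 0.227). That test takes the genes as independent although all were measured in the same pools, so its p-value does not measure the spread between pools. Pieces taken from another part of the small intestine cannot be told apart from a treatment effect, since these genes went both ways and no label names the part taken. Earlier maturation under arsenic is therefore one candidate explanation and position another, and the labels hold no older group to set them against.

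Most T and NK cell, macrophage and interferon genes were lower in arsenic. Dilution of all non-epithelial cells by more epithelium is argued against, because the T and NK cell mean fell relative to the mean of the smooth muscle, fibroblast and nerve lists, by -0.97 on the log2 scale and in every arsenic pool (exact permutation test, two-sided, p = 0.0286). With the endothelial list, which fell as well (-0.39 relative to those 3 lists), added to the comparison the fall was -0.88 (exact permutation test, two-sided, p = 0.0286). Macrophage genes (8 of 10 lower, 0 higher) and collagen genes (26 of 42 lower, 3 higher) also fell. A dilution that spared smooth muscle was not tested and stays open. Loss of the RNA of T, NK and B cells and macrophages is argued against as the whole cause of the lower interferon genes, because the interferon mean fell relative to the mean of these immune lists by -1.17, and relative to the T and NK cell list alone by -0.83, in every arsenic pool (exact permutation test, two-sided, p = 0.0286 each). Fewer cells that make interferon, or a weaker response in the remaining cells, may contribute and stay open, and the T and NK cell genes were low, with a median of 1.22 CPM over the list's vehicle means.

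Single libraries stood apart from the other 3 of their group in 16 of 450 sets of 4 values (3.56%, where chance gives about 5%), by a gap that took more of the group's range than Dixon's 95% critical value. Vehicle replicate 1 was the one apart in 5 of them. Its share of counts in the 10 most abundant genes was 7.33% against 8.70% to 8.84% (gap 0.907), with Cd36 at 144 against 176 to 182 CPM (0.831), Pdk4 at 114 against 140 to 145 CPM (0.831), Fgf15 at 94.7 against 77.3 to 79.3 CPM (0.885) and Npas2 at 47.3 against 52.7 to 53.6 CPM (0.860). In vehicle replicate 2 Col6a1 was low at 310 CPM (0.924) and Nfe2l2 high at 266 CPM (0.877), and in vehicle replicate 3 Dio3os was high at 12.8 CPM (0.876). Arsenic replicate 1 was high for Gsta4 at 188 against 156 to 160 CPM (0.885) and for Nrg1 at 19.2 CPM (0.945). Arsenic replicate 3 was high for Lgr5 at 29.4 CPM (0.834) and Gfap at 1.59 CPM (0.975) and low for Onecut2 at 109 CPM (0.923). Arsenic replicate 4 was high for Cd36 at 88.0 CPM (0.863) and for the acinar gene Cela1 at 684 against 271 to 325 CPM (0.869), and low for Shmt2 at 85.6 CPM (0.905).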

How the results depend on the processing

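Chosen only after the result was seen were the fits with Y-linked expression, without both pools that looked single-sex, and with GC content and length trends removed. No paired analysis was possible because the labels share no replicate numbers between the groups. Across scalings, filters, left-out libraries and tools other than the test against a fold, between 4626 and 5311 genes were higher and between 4481 and 5408 lower, and 92.4% or more of the calls were shared under every planned one of these, and 91.3% or more under those added. All scalings used centre the bulk of genes near no change, so these settings do not test that assumption. With upper-quartile factors 4626 genes were higher and 5408 lower, against 4944 and 5053 by TMM. The test against a 1.5-fold change (glmTreat) kept 815 higher and 814 lower, by its construction, since most changes were smaller. Of 203 named genes past the threshold, 192 kept direction and threshold in each of the 19 other settings that tested them, 7 named genes being untested at a minimum of 1 CPM in 4 libraries. Camera called 16 lists and camera with an estimated correlation called 0 (4 at an unadjusted p under 0.05), as the preset assumes nearly independent genes. The 33 lists called by fry answer another question, since fry does not compare a list with other genes. Of the 16 lists, adult-type and proximal genes lost their camera call with a surrogate variable, adult-type and T and NK cell genes at a minimum of 1 CPM and proximal genes without arsenic replicate 3, and the camera direction of the lists not called was not followed, because it changed sign for several of them. With GC content and length trends removed, 5 genes past the threshold were past it in the other direction, and Col3a1 moved to log2 0.018 and Col6a1 to 0.051, neither called in the comparison of all libraries by TMM or with these trends removed. Without both pools that looked single-sex, Ddx3y stood at -0.28, Eif2s3y at -0.20, Kdm5d at -0.47, Xist at 0.13 and the mast cell gene Cpa3 at 0.12, and Kdm5d stood at -0.11 with the Y-linked covariate. For the sex-linked genes these settings remove the pools, or the trend, that carry their differences by construction. With 1 library left out, Cpa3 ranged from -0.37 to 0.21 and Kdm5d from -0.077 to 0.77, and none of these passed. The cause for Cpa3 was not tested. List counts that moved by more than 1 member on leaving out a library, among those of at most 2 members, were those of acinar genes lower (6 without arsenic replicate 4) and higher (4 without vehicle replicate 2), fibroblast genes lower (4 without arsenic replicate 3, 0 without vehicle replicate 3, arsenic replicate 2 or arsenic replicate 4) and nerve genes higher (3 without vehicle replicate 4). Depth limits the precision of low-level genes, and 5 of 9 T and NK cell genes did not reach 1 CPM in 4 libraries and were not tested under that minimum.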

Other observations

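The gene families here were grouped by symbol and tested only after the result was seen, and the iron, gasdermin and sex observations were also picked after their values were seen.

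Several gene families held mostly higher genes in arsenic, among them those of the cytosolic and mitochondrial ribosome. All 46 tested cytosolic large-subunit ribosomal genes (Rpl) rose with a median log2 change of 0.47, and 30 of 35 small-subunit genes (Rps) rose with 1 lower. Mitochondrial ribosomal genes rose in 46 of 48 cases (Mrpl) and in 29 of 29 (Mrps), mitochondrial import genes (Timm) in 13 of 13 at a median of 0.75, proteasome lid and base genes (Psmd) in 13 of 14 and nucleoporins (Nup) in 19 of 20. Genes with symbols starting Eif, which are not all translation initiation factors, rose in 39 of 52 cases with 5 lower. Ube genes rose in 25 of 38 cases with 7 lower. Proteasome core genes (Psmb) stood at 7 higher and 3 lower of 10, a family that did not pass camera (adjusted p = 0.150), nor did Usp, with 18 higher and 12 lower of 45 (adjusted p = 0.537), or Rnf, with 12 higher and 34 lower of 73 (adjusted p = 0.0625). Rpl10 went from 382 ± 10.1 to 516 ± 8.93 CPM and Mrpl12 from 82.8 ± 3.97 to 159 ± 2.59 CPM (n = 4 pools each), and Psmd14 rose 1.82-fold. With GC content and length trends removed, 43 Rpl genes and 44 Mrpl genes were higher. In the other direction the guanylate-binding proteins (Gbp) fell in 9 of 9 cases with a median of -0.83, the apolipoprotein L genes (Apol) in 8 of 8 with a median of -1.17, collagens (Col) in 26 of 42 with 3 higher, and zinc finger genes (Zfp) in 161 of 342 with 31 higher. The last pair depended more on that correction, with 9 Col genes higher and 21 lower (median -0.22 against -0.35) and 37 Zfp genes higher and 139 lower when the trends were removed. Camera over 247 families gave adjusted p = 2.18e-11 for Rpl and 4.03e-13 for Mrpl, and adjusted p = 0.454 and 0.403 with an estimated correlation, which no family passed. Ribosomal genes have many pseudogenes and Apol and Gbp genes have close relatives, so counts of single members are uncertain.

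Among the 11 genes of the iron and heme list, 4 higher and 5 lower (camera adjusted p = 0.990), the largest changes were falls of a reductase, an exporter and an importer of iron and a rise of the transferrin receptor. Cybrd1 fell by 3.35, Slc40a1 by 1.65 and Slc11a2 by 1.47 on the log2 scale, and Tfrc, which takes up iron from blood, rose from 149 ± 13.6 to 298 ± 12.4 CPM. Cybrd1 and Slc40a1 are also members of the proximal list, so their falls are the same changes as those given there. The gasdermin genes Gsdmc2, Gsdmc3 and Gsdmc4, neighbours on chromosome 15, were 5.43-fold, 6.73-fold and 6.48-fold lower, and Gsdmc4 went from 41.9 ± 2.55 to 6.55 ± 1.22 CPM.

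The pools differed in sex makeup. Summed Y-linked expression was 142, 122, 63.6 and 0.529 CPM in the vehicle pools and 58.4, 60.0, 204 and 143 CPM in the arsenic pools, while Xist stood at 464, 605, 965 and 1386 CPM and at 917, 906, 10.1 and 384 CPM. Vehicle replicate 4 had almost no Y-linked counts and arsenic replicate 3 almost no Xist. Ass1 and Eno1 had 3 counts each over all libraries and the 4 listed globin genes 0, while Eno1b had 0.542 ± 0.154 CPM with vehicle and 1.06 ± 0.153 CPM with arsenic.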
